A study of Rattus norvegicus with 23 samples.

How the data were processed

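RNA was sequenced in 23 rat libraries of 6 groups: differentiating CG4 cells with a control vector, Zfp488 or Nkx2.2 (4 libraries each), proliferating CG4 cells (3), and differentiating and proliferating primary oligodendroglia (4 each). The deposited files hold raw read counts per gene, 1 library per file, which the authors made from the reads. Their notes name Trimmomatic 0.36, STAR 2.5.2b, featureCounts of Subread 1.5.2 and the genome build rn6, without their parameters. The annotation release, the use of strand and the treatment of reads with several matches are not given in the sources used here, so values of overlapping, antisense and near-identical genes are uncertain. The authors also deposited a table per factor with log2 fold changes and p-values, raw and adjusted, which their notes attribute to DESeq2. The same tables hold a normalized signal for 16 columns, which by the values is each library's count divided by 1 size factor of the authors. These tables were used for gene names and for the comparison at the end of the results, and all other values were computed from the counts.

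Gene names came only from the authors' tables, which name 14690 identifiers and 12432 of those in both gene lists, leaving 2787 without a name. These tables cover differentiating CG4 cells, so genes counted mainly in primary cells can lack a name. Genes without a name entered no list and were not named here, among them 532 genes called in primary differentiation. The supplied table of gene names matched 0 identifiers, so no positions are given. Of the named identifiers 210 shared their symbol with another identifier, and symbols turned into dates were not used.

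Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, filterByExpr, two-sided, Benjamini-Hochberg adjusted p under 0.05). The 12 differentiating CG4 libraries shared 1 fit, the 8 primary libraries another, and the control and proliferating CG4 libraries a further one. The difference of the differentiation responses was an interaction term in a fit of the primary, control and proliferating CG4 libraries. CPM are scaled by the library totals after TMM. The p-values measure only the spread between these libraries, which the titles call biological replicates. The 23 gene lists were fixed before the data were examined and tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, then with a correlation estimated from the residuals, with fry, and with the replicate block, with adjustment over the lists of a comparison. Counts of list members are given over all genes tested and adjusted over the list alone. Correlations of responses used differences of mean log2 CPM, with an exact permutation of library labels where no library was shared. Log2 CPM held a prior count of 2, which does not enter the log2 fold changes of the edgeR fits. Where controls were shared, the controls and unchanged groups were all simulated from the control means with seed 20240.

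Genes are named by a rule fixed before the data were examined. It takes a fixed panel, of which 12 genes are given (Zfp488, Nkx2-2, Olig1, Olig2, Sox10, Myrf, Mbp, Mog, Pdgfra, Cspg4, Mki67 and Gfap). It adds the 8 largest rises and falls per comparison among genes with an adjusted p under 0.05, a mean of at least 5 CPM, groups that do not overlap and a gene symbol, with no demand on overlap for the interaction. It adds up to 4 members per list with the smallest adjusted p, and the text gives a part of the genes the rule selects. The levels of Fdps, Tf and E2f1, of the genes over 8-fold outside the other groups in proliferating CG4 cells and of microglia markers were chosen after their values were seen.

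Replicate numbers were checked by correlating the deviations of same-numbered libraries from their group means. In differentiating CG4 cells every pair lay over 0.1 (Zfp488 and control 0.192 to 0.690, Nkx2.2 and control 0.143 to 0.554, Zfp488 and Nkx2.2 0.264 to 0.559), so the numbers pair these libraries, though the labels do not say what a number marks. Replicates of every group differed by more than counting noise (chi-square over degrees of freedom of 1.74 to 254). The differentiating primary libraries form 2 close pairs, with 8.16 between libraries 1 and 2, 1.74 between 3 and 4 and 28.1 to 35.5 across the pairs. The labels do not say what the pairs share, and the tests treat all 4 as replicates. Nkx2-2, for example, stood at 45.0 and 38.4 CPM in the first pair and 93.0 and 86.6 CPM in the other.

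The alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, counts thinned to the smallest library, the replicate number as a block, other sets of libraries or genes in the fit, and leaving out each library in turn. For CG4 differentiation the block fit left out control replicate 4. The procedure was tested on simulated data with known changes. At a log2 change of 1 it recovered 85.1% for Zfp488, 82.1% for Nkx2.2 and for the direct comparison, 98.5% for primary cells, 32.8% for CG4 differentiation and 49.3% for the interaction. At 0.5 it recovered 25.4%, 22.4%, 31.3%, 79.1%, 2.99% and 7.46%. Each simulation changed 67 genes at each of these sizes, a far smaller share than was called in the data, and had no pairing by number. With so few changed genes the adjusted threshold is stricter, so these shares do not give the power of the tests on the data. A gene at 0 in all libraries of a group is compared with a floor of 3 counts per library, which covers counting error only.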

Results

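RNA was sequenced in 23 rat libraries that fall into 6 groups. CG4 is a cell line derived from rat brain oligodendroglia. Of its libraries, 12 came from cells differentiated for 3 days after transduction with a GFP vector (control), Zfp488 or Nkx2.2, with 4 libraries per group. Another 3 came from proliferating CG4 cells without a vector. Primary oligodendroglia, shaken off mixed glial cultures, gave 4 proliferating and 4 differentiating libraries. Total counts per library were 39268564 to 49206479 in control, 29906831 to 43307908 in Zfp488, 31112360 to 40854053 in Nkx2.2 and 32454992 to 42318101 in proliferating CG4 cells. They were 22624183 to 36301186 in differentiating and 20063345 to 33130502 in proliferating primary cells. The files of differentiating CG4 cells list more genes than the others, and the genes listed only there held 8.24% to 10.5% of their counts. Levels are CPM, counts scaled to equal library totals, as mean ± SD, and changes are log2 fold changes ± SE with the adjusted p of edgeR's quasi-likelihood test.

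The introduced genes were read first. Zfp488 (ENSRNOG00000057542), a zinc finger transcriptional regulator of oligodendroglia, lay at 155 ± 26.6 CPM (n = 4) in the Zfp488 libraries and 39.1 ± 10.3 CPM (n = 4) in control. Nkx2-2 (ENSRNOG00000012728), the gene of the homeodomain factor Nkx2.2, lay at 1510 ± 291 CPM (n = 4) in the Nkx2.2 libraries and 249.9 ± 39.1 CPM (n = 4) in control. Every library of each factor lay above every control library for its own gene.

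**Figure D1:**
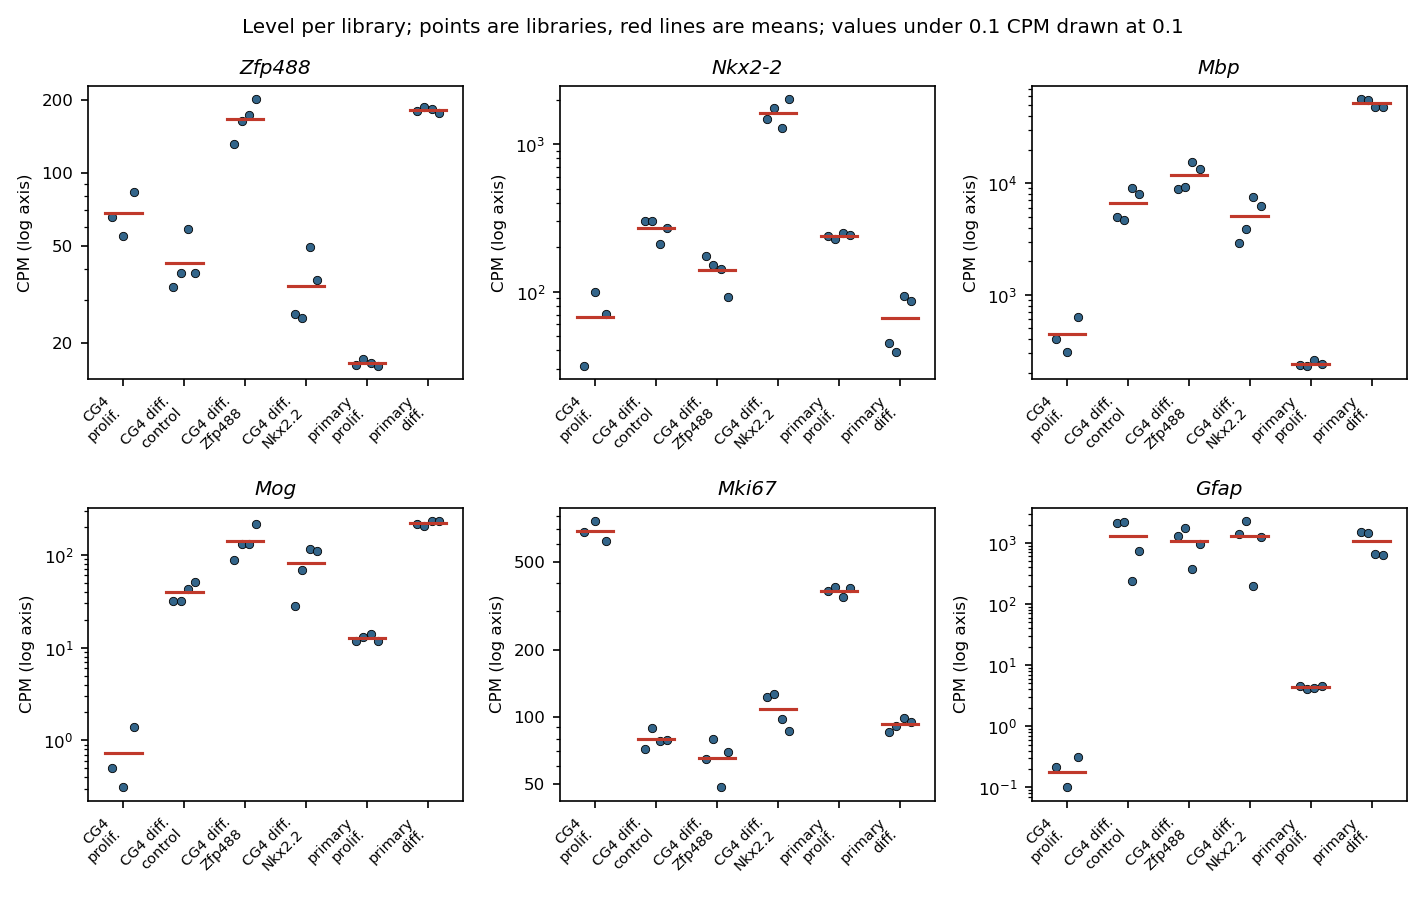
Level of 6 genes in each library (CPM, log axis) for the 6 groups, with all 23 libraries scaled over the genes their files share, so that values differ from those in the text; points are libraries and red lines are group means. On this scale the Zfp488 libraries lie between 131 and 201 CPM of Zfp488 and the Nkx2.2 libraries between 1289 and 2009 CPM of Nkx2-2.

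The comparison of Zfp488 with control asks which genes change when differentiating CG4 cells carry added Zfp488. Some genes of mature oligodendrocytes rose. Mog (ENSRNOG00000000775), a myelin surface glycoprotein, rose by 1.85 ± 0.39 on the log2 scale, from 36.5 ± 9.10 to 131 ± 49.3 CPM (n = 4 and 4, adjusted p = 0.0148). Mbp stood at 10957 ± 3066 against 6153 ± 2075 CPM, a log2 difference of 0.83 ± 0.32 that passed only with the replicate number as a block (adjusted p = 0.129 without the block and 0.000447 with it). Myrf, the transcription factor of myelin genes, differed by 0.72 ± 0.21 (adjusted p just above 0.05 without the block and 0.00336 with it). Nkx2-2 fell by 0.94 ± 0.20, to 130 ± 32.9 CPM (adjusted p = 0.0140), and Olig1 fell by 0.89 ± 0.17, from 402 ± 56.5 to 217 ± 40.9 CPM (adjusted p = 0.0105). Olig2 differed by -0.52 ± 0.17 (adjusted p = 0.0836, and 0.00498 with the block). Sox10 (0.05 ± 0.10), Pdgfra (0.09 ± 0.24), Cspg4 (0.26 ± 0.36), Mki67 (-0.27 ± 0.15) and Gfap (-0.26 ± 0.73) did not pass, with adjusted p from 0.294 to 0.869. One control library lay apart from the others for Sox10.

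Among genes with a mean of at least 5 CPM, the 8 largest rises with Zfp488 were those of Col6a2, a chain of collagen VI (3.28 ± 0.44, adjusted p = 0.00227), Kndc1 (3.09 ± 0.71), the myelin protein gene Opalin (2.96 ± 0.68), Chst8 (2.93 ± 0.60), Lpar3, a receptor of lysophosphatidic acid (2.90 ± 0.59), Klhl40 (2.86 ± 0.59), Cdc42ep2 (2.85 ± 0.54) and Atp2a3 (2.73 ± 0.65). Opalin went from 6.39 ± 1.74 to 49.6 ± 23.7 CPM. The 8 largest falls were those of Adcyap1r1, the receptor of the neuropeptide PACAP (-2.16 ± 0.23, adjusted p = 0.00102), Lrrtm4 (-1.76 ± 0.27), Ror2, a receptor of Wnt ligands (-1.53 ± 0.17), Zim1 (-1.45 ± 0.39), St8sia1 (-1.35 ± 0.24), Fbln7 (-1.34 ± 0.18), Tox (-1.32 ± 0.15) and Tmem117 (-1.27 ± 0.13).

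Of 33 tested genes of the myelin and mature oligodendrocyte list, 8 rose and 2 fell, or 15 and 2 adjusted over the list alone and 21 and 4 with the replicate block. As a set they were higher than other genes (adjusted p = 1.69e-05, but adjusted p = 0.451 with an estimated correlation). Aspa, which breaks down N-acetylaspartate, rose by 1.51 ± 0.20 (adjusted p = 0.00201), and Gsn rose by 1.13 ± 0.16 (adjusted p = 0.00322), while Plekhb1 fell by 0.77 ± 0.14. Among 27 oligodendrocyte progenitor genes 1 rose and 5 fell, or 3 and 8 adjusted over the list alone. That list was lower (adjusted p = 0.00994, and 0.200 with an estimated correlation), and C1ql1 fell by 0.74 ± 0.16 from 66.1 ± 9.26 CPM.

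Interferon response genes rose in 10 of 24 members with none falling, 12 adjusted over the list alone (list adjusted p = 1.69e-05, and 0.160 with an estimated correlation). Gbp2, a guanylate-binding protein, went from 0.36 ± 0.0339 to 1.55 ± 0.488 CPM, and B2m, the light chain of MHC class I, from 189 ± 21.0 to 293 ± 34.9 CPM. Of 12 p53 targets 4 rose and none fell, 5 adjusted over the list alone (list adjusted p = 0.00558, and 0.200 with an estimated correlation). They included Phlda3, up 2.02 ± 0.32, and Ccng1, up 0.70 ± 0.11. Of 22 genes of the integrated stress and unfolded protein response 5 rose, 6 adjusted over the list alone (list adjusted p = 0.0133, and 0.409 with an estimated correlation). Ddit3 rose by 0.89 ± 0.12 and Trib3 by 1.19 ± 0.23. Lists of other cell types moved in the same libraries. Fibroblast, pericyte and endothelial genes rose in 2 of 8 members (list adjusted p = 0.0260, and 0.381 with an estimated correlation), with Col3a1 from 0.147 ± 0.0723 to 6.92 ± 6.23 CPM and Fn1 up 1.97 ± 0.48. Schwann cell and neural crest genes rose in 2 of 11 (list adjusted p = 0.0485, and 0.256 with an estimated correlation), with the neurotrophin receptor gene Ngfr up 2.40 ± 0.39 and Pmp22 up 0.53 ± 0.11. Of 19 genes of ERK pathway feedback 2 rose (list adjusted p = 0.0370, and 0.617 with an estimated correlation). The 13 mitochondrially encoded genes were lower as a set, with a median of -0.22 (adjusted p = 0.0439, and 0.679 with an estimated correlation). The other 14 lists did not pass, except that the thyroid hormone response list passed with the block (adjusted p = 0.0332, but 0.409 with an estimated correlation and 0.199 with both).

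Of 14811 genes tested, 1339 passed with Zfp488, 873 higher and 466 lower, and 401 of them differed by at least 1 on the log2 scale. The replicate number as a block gave 3576 genes, 2071 higher and 1505 lower, with all 1339 among them and none in the opposite direction. DESeq2 gave 2116. The count was 877, 800 and 669 without control replicate 1, 2 and 3, and 620 and 458 without Zfp488 replicate 2 and 4. Leaving out 1 library ended some calls. Mog, C1ql1 and Pmp22 no longer passed without Zfp488 replicate 4 (adjusted p = 0.0525). Opalin no longer passed without control 1 or 3 or Zfp488 2 or 4 (up to 0.0678). Kndc1 no longer passed without control 1 or 2 or Zfp488 4 (up to 0.0704), and Atp2a3 without control 1, 2 or 3 or Zfp488 4 (up to 0.0801) or without the libraries numbered 3. The same held for Fn1 without control 1, 2 or 3 or Zfp488 1, 2 or 4 (up to 0.0723). Zim1 no longer passed without control 1, 2 or 3, Zfp488 1, 2 or 4 or Nkx2.2 2 or 4 (up to 0.128), nor at equal depth or with only the 8 libraries compared.

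**Figure D2:**
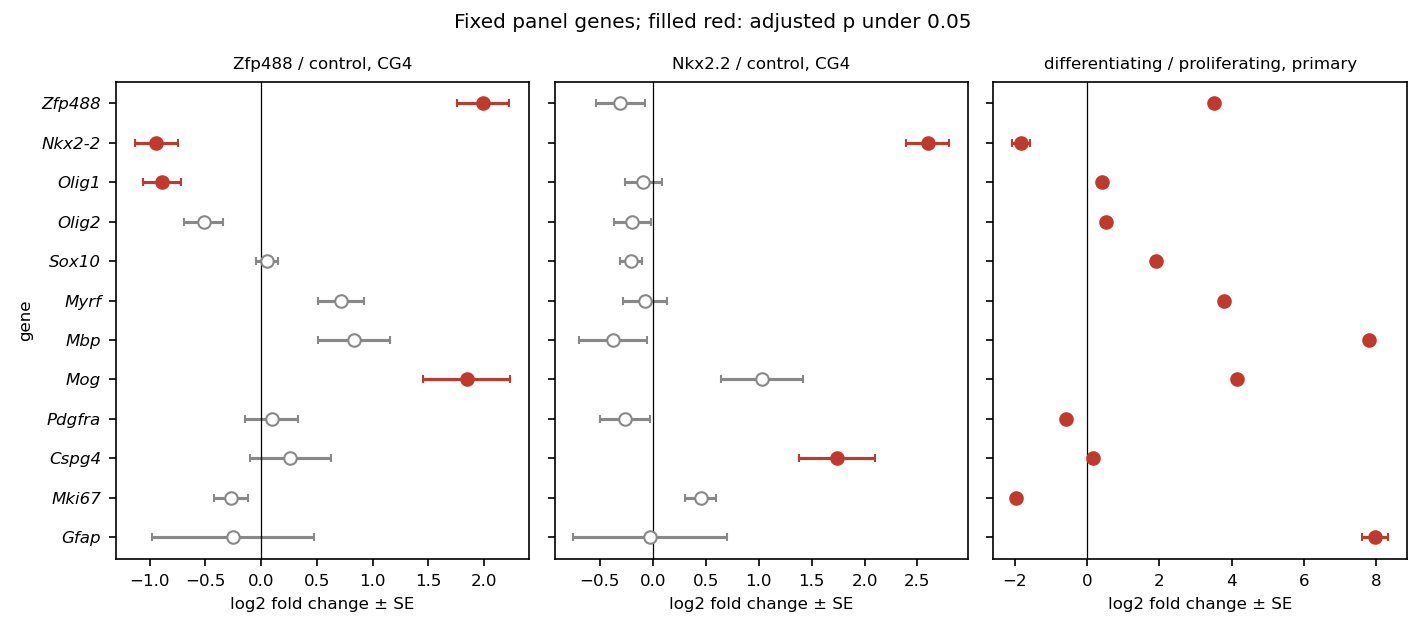
Log2 fold change ± SE of 12 fixed panel genes for Zfp488 against control and Nkx2.2 against control in differentiating CG4 cells and for differentiating against proliferating primary cells; filled red points have an adjusted p under 0.05. Mog lies at 1.85 with Zfp488, 1.03 with Nkx2.2 and 4.17 in primary differentiation.

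The comparison of Nkx2.2 with control asks the same of added Nkx2.2. Nkx2-2 itself rose by 2.60 ± 0.21 (adjusted p = 1.66e-05). Of the other panel genes only Cspg4, the NG2 proteoglycan of progenitors, passed without the block, going from 1.49 ± 0.362 to 4.99 ± 2.2 CPM (1.74 ± 0.36, adjusted p = 0.00823). With the block, Mbp (-0.38 ± 0.32, adjusted p = 0.502 without the block and 0.0163 with it), Mog (1.03 ± 0.38, 0.111 and 0.0112) and the proliferation marker Mki67 (0.45 ± 0.15, 0.0745 and 0.0160) passed. Zfp488 (-0.31 ± 0.23), Olig1 (-0.09 ± 0.17), Olig2 (-0.19 ± 0.17), Sox10 (-0.21 ± 0.10), Myrf (-0.08 ± 0.21), Pdgfra (-0.26 ± 0.24) and Gfap (-0.03 ± 0.73) did not pass in either fit. One Nkx2.2 library lay apart from the others for Olig1.

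Among the 8 largest rises with Nkx2.2, for genes with a mean of at least 5 CPM, Lcn2 (ENSRNOG00000013973), which encodes lipocalin 2, went from 0.245 ± 0.0827 to 31.1 ± 12.2 CPM (6.97 ± 0.39, adjusted p = 1.37e-06). Islr rose by 6.21 ± 0.41, Chi3l1 by 5.77 ± 0.39, Scara5 by 5.71 ± 0.62, Clec3a by 5.54 ± 0.56, Mia by 4.64 ± 0.30 and Boc, a co-receptor of hedgehog signals, by 4.62 ± 0.40. The 8 largest falls were those of Spon2 (-2.67 ± 0.73), the hyaluronan synthase gene Has2 (-2.44 ± 0.30, adjusted p = 0.000352), Gng4 (-2.31 ± 0.30), Igfbp3 (-2.19 ± 0.44), Mir675 (-2.12 ± 0.54), Vwc2 (-2.06 ± 0.40), Ntn4 (-1.85 ± 0.35) and Fam19a2 (-1.81 ± 0.50). Mir675 lies within the transcript of H19, so its counts cannot be told from those of its host.

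Wnt pathway targets rose in 6 of 10 members and fell in 1, or 6 and 2 adjusted over the list alone. This list alone in the comparison also passed with an estimated correlation (adjusted p = 8.68e-08 with the preset and 0.00385 with the estimated correlation). The members with the smallest adjusted p encode inhibitors of the pathway, as do many genes of this fixed list. Wif1 (ENSRNOG00000004476), a secreted Wnt antagonist, went from 4.38 ± 1.52 to 75.4 ± 16.7 CPM (4.10 ± 0.25, adjusted p = 2.44e-06), and Nkd1 from 5.57 ± 0.366 to 20.2 ± 2.76 CPM. Of 35 cell cycle genes 4 rose and none fell, or 20 and none adjusted over the list alone and 15 and none with the block (list adjusted p = 8e-07, and 0.470 with an estimated correlation). Ccne2 rose by 0.42 ± 0.11 and Ccnb1 by 0.52 ± 0.14. Of 19 glycolysis genes 5 fell, 8 adjusted over the list alone (list adjusted p = 0.000235, and 0.449 with an estimated correlation). The muscle-type phosphofructokinase gene Pfkm fell by 0.96 ± 0.10, from 176 ± 17.9 to 90.5 ± 7.37 CPM, and the lactate dehydrogenase gene Ldha fell by 0.73 ± 0.11, from 2961 ± 123 to 1785 ± 286 CPM.

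Of 24 fatty acid and sphingolipid synthesis genes 3 fell, 4 adjusted over the list alone (list adjusted p = 0.00609, and 0.489 with an estimated correlation), among them Kdsr, down by a log2 change of -1.06 ± 0.15, and Elovl5, at -0.39 ± 0.07. Committed or premyelinating oligodendrocyte genes fell in 3 of 15 and rose in 1, or 5 and 1 adjusted over the list alone (list adjusted p = 0.0291, and 0.579 with an estimated correlation), with the kinase gene Fyn at -0.51 ± 0.13 and Ninj2 at -0.72 ± 0.19. Notch pathway targets rose in 3 of 9 (list adjusted p = 0.0274, and 0.216 with an estimated correlation). Hes1, a Notch-induced repressor, went from 3.00 ± 0.310 to 11.8 ± 3.33 CPM, and Notch1 rose by 0.49 ± 0.10. Of 19 ERK feedback genes 2 rose, Phlda1 by 1.37 ± 0.27 and Etv5 by 0.71 ± 0.15, or 3 adjusted over the list alone (list adjusted p = 0.0347, and 0.579 with an estimated correlation). Fibroblast, pericyte and endothelial genes rose in 3 of 8 and fell in 1, or 4 and 1 adjusted over the list alone (list adjusted p = 0.0347, and 0.449 with an estimated correlation), with fibronectin, Fn1, from 8.0 ± 2.41 to 84.0 ± 39.6 CPM and Thbs1 up 2.95 ± 0.40. The BMP pathway list passed only with the block (adjusted p = 0.0636 without it and 0.00133 with it, but 0.449 with an estimated correlation and 0.165 with both). The myelin list moved both ways, with 5 of 33 members higher and 4 lower (adjusted p = 0.791, median -0.03, mean 0.23). Pmp22 rose by 0.95 ± 0.11 and Apod by 1.57 ± 0.20. Of 27 progenitor genes 5 rose and 5 fell, or 5 and 8 adjusted over the list alone (adjusted p = 0.851, median -0.19, mean 0.08), with the transcription factor Sox5 up 2.59 ± 0.26 and Id4 up 1.99 ± 0.22. The Schwann cell list held 3 rises and 3 falls among 11 genes, or 4 and 5 adjusted over the list alone (adjusted p = 0.900).

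With Nkx2.2, 1567 of 14811 genes passed, 904 higher and 663 lower, and 699 differed by at least 1 on the log2 scale. The replicate block gave 3876 genes, of which 1872 were higher and 2004 lower, and all 1567 were among them. The share higher was 57.7% without the block and 48.3% with it. The count was 974 and 924 without Nkx2.2 replicate 2 and 4. Leaving out 1 library also ended the calls of Ccne2 without control 1 or 2 or Nkx2.2 1, 2 or 4 (up to 0.0718), Ccnb1 without control 1, 2 or 3 or Nkx2.2 1, 2 or 3 (up to 0.108), or all libraries numbered 3, and Fyn without control 1 or 3 or Nkx2.2 1, 2 or 4 (up to 0.0815). Ninj2 ended without control 3 or 4 or Nkx2.2 1, 2 or 4 (up to 0.0840), Mir675 without control 2 or Nkx2.2 1 or 4 (up to 0.0788), Fam19a2 without control 2 or 3 or Nkx2.2 1, 2 or 4 (up to 0.109) and Spon2 without control 2 or 4, Zfp488 2 or Nkx2.2 1, 2 or 4 (up to 0.105). Fam19a2 and Spon2 also no longer passed with only the 8 libraries compared.

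**Figure D3:**
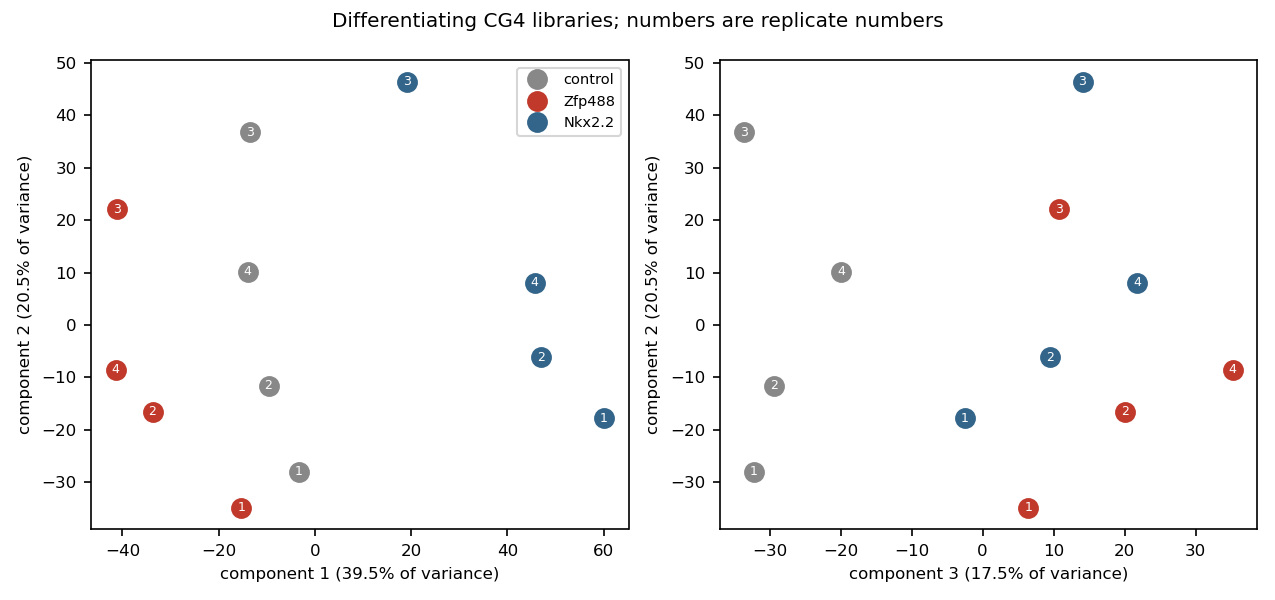
The 12 differentiating CG4 libraries on their first 3 principal components, which hold 39.5%, 20.5% and 17.5% of the variance; colours are groups and the printed digits are replicate numbers. Nkx2.2 lies apart on component 1, control lies below the other groups on component 3, and libraries numbered 3 lie highest on component 2 in every group.

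The direct comparison of Zfp488 with Nkx2.2 asks where the factors differ. Mbp was higher with Zfp488 by 1.21 ± 0.32 (adjusted p = 0.0173) and Myrf by 0.79 ± 0.21 (adjusted p = 0.0155). Olig1 was lower by a log2 change of -0.80 ± 0.17, Mki67 by -0.72 ± 0.15 and Cspg4 by -1.48 ± 0.36. Zfp488 (2.29 ± 0.24) and Nkx2-2 (-3.53 ± 0.22) differed as introduced. Mog differed by 0.81 ± 0.38 (adjusted p = 0.135, and 0.00663 with the block), Sox10 by 0.26 ± 0.10 (0.0757, and 0.0133 with the block), Olig2 by -0.32 ± 0.17 (0.186, and 0.0345 with the block) and Pdgfra by 0.35 ± 0.24 (0.294, and 0.0124 with the block), while Gfap differed by -0.23 ± 0.73 (0.840). The largest differences toward Zfp488 included Lpar3 (4.04 ± 0.65), Spon2 (3.75 ± 0.76), Cxcl14 (3.43 ± 0.59), Baalc (3.36 ± 0.36), Nov (3.35 ± 0.89), Armc4 (3.13 ± 0.34) and Sod3 (3.10 ± 0.31). Toward Nkx2.2 they included Lcn2 (-6.97 ± 0.39), Chi3l1 (-5.76 ± 0.40), Islr (-5.42 ± 0.39), Ncmap (-5.41 ± 0.51), Clec3a (-4.93 ± 0.54), Scara5 (-4.91 ± 0.60) and Boc (-4.40 ± 0.40).

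Glycolysis genes were higher with Zfp488 in 12 of 19 and lower in 2, or 14 and 2 adjusted over the list alone (list adjusted p = 1.03e-05, and 0.256 with an estimated correlation). Ldha differed by 0.97 ± 0.11, at 3491 ± 154 against 1785 ± 286 CPM, and Pfkm by 0.88 ± 0.10. Cell cycle genes were lower in 15 of 35 and higher in none, or 23 and none adjusted over the list alone (list adjusted p = 3.58e-06, and 0.549 with an estimated correlation), with Ccne2 at -0.44 ± 0.11. The myelin list was higher in 12 of 33 and lower in 3, or 18 and 4 adjusted over the list alone (list adjusted p = 0.00678, and 0.589 with an estimated correlation). Gsn differed by 1.26 ± 0.16 and Aspa by 1.44 ± 0.20, and Apod by -2.42 ± 0.20. Fatty acid and sphingolipid genes were higher in 8 of 24 (list adjusted p = 0.00678, and 0.569 with an estimated correlation), led by Kdsr at 1.32 ± 0.15 and Elovl5 at 0.41 ± 0.07, and cholesterol synthesis genes in 4 of 23 (0.0352, and 0.694), led by Sc5d at 0.45 ± 0.09. Wnt targets were lower in 5 of 10 and higher in 2 (0.00551, and 0.168), with Wif1 at -3.79 ± 0.25 and Nkd1 at -1.10 ± 0.12. BMP pathway genes were lower in 5 of 10 (0.0152, and 0.256), with Bambi at -1.25 ± 0.15 and Id4 at -1.42 ± 0.21. Progenitor genes were lower in 10 of 27 and higher in 3 (0.0352, and 0.256), with Sox5 at -2.62 ± 0.26 and Cdo1 at -1.90 ± 0.20. Of 12 p53 targets 5 were higher (0.00343, and 0.238), led by the death receptor gene Fas at 1.51 ± 0.21 and Phlda3 at 2.19 ± 0.32. Premyelinating genes were higher in 5 of 15 (0.0326, and 0.589), with Fyn at 0.72 ± 0.13 and Ninj2 at 0.75 ± 0.19. Interferon genes were higher in 7 of 24 and lower in 1 (0.0326, and 0.317, but 0.0597 with the block), with Mx2 at 1.5 ± 0.17 and Ifit2 at 1.63 ± 0.21. Mitochondrially encoded genes were lower in 4 of 13 (0.0352, and 0.653), with Mt-nd4l at -0.48 ± 0.11 and Mt-nd5 at -0.43 ± 0.12. The Notch list passed only with the block (adjusted p = 0.0796 without it and 0.0220 with it, but 0.256 with an estimated correlation and 0.173 with both), and so did the Schwann cell list (0.210 and 0.0477, but 0.549 and 0.241). Adjusted over the list alone, 12 fatty acid genes were higher, 6 Wnt genes were lower and 2 higher, 6 BMP genes lower and 1 higher, 11 progenitor genes lower and 4 higher and 7 p53 targets higher, and the counts of the cholesterol, premyelinating, interferon and mitochondrial lists were the same. In each bracket the first value is the list's adjusted p and the second the adjusted p with an estimated correlation, except for the Notch and Schwann cell lists.

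Between the factors 3741 of 14811 genes passed, 1966 higher with Zfp488 and 1775 lower, and 6276 with the replicate block, 3264 higher and 3012 lower, with all 3741 among them. Mbp no longer passed without Nkx2.2 replicate 2 (adjusted p = 0.0531), nor Mt-nd5 without Zfp488 replicate 4 (0.0604).

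Both factors were compared with the same controls, so their responses share those controls' chance values. Across 14811 genes, which are not independent replicates, the log2 changes with Zfp488 and with Nkx2.2 correlated at r = 0.170. Unchanged groups with shared controls, all simulated from the control means, gave 0.487 (0.457 to 0.517 over 200 simulations). With the controls split 2 and 2, r averaged 0.0514 (-0.0289 to 0.154 over 6 splits). The covariance was 0.0412 against 0.0288 simulated (0.0263 to 0.0311), a difference of 0.0124, and averaged 0.0130 with split controls (-0.0085 to 0.0375). The same direction was seen in 53.1% of genes against 66.4% simulated. Calls coincided as 127 genes higher with both factors (53.3 for independent lists), 60 lower with both (20.9), 64 higher with Zfp488 and lower with Nkx2.2 (39.1) and 35 the other way (28.4). Unchanged groups simulated in that way gave 0 shared calls in each of 20 simulations, with at most 1 call per factor. Where as many top genes as were called were taken from them by p, 268 and 123 coincided on average in the same direction and 3.50 and 2.65 in opposite directions. With the controls split 2 and 2, which leaves fewer calls, 25 and 8.33 coincided on average in the same direction (9.41 and 4.2 for independent lists) and 24.5 and 11.5 in opposite directions (7.04 and 5.52). The simulated groups carry no effects of their own, so their r, shared directions and top genes show the shared controls alone. The split overlaps are observed values and not chance values. These values therefore cannot decide on a shared effect, and none is called. These simulations and splits leave out the pairing by number. With number effects simulated in every group, r was 0.476 (0.445 to 0.499), the covariance 0.0148 (0.0132 to 0.0159), a difference of 0.0264 from the observed one, and the same direction held in 66.2% of genes. Shared calls were again 0, with 268 and 127 of the top genes coinciding in the same direction. With control splits that keep the pairs, r averaged 0.103 (-0.0446 to 0.230) and the covariance 0.0259 (-0.0140 to 0.0574). The observed covariance thus lies above every simulation of either kind, while its split values range across 0. The simulated and split overlaps and the paired versions were added after the results were seen.

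Differentiating against proliferating primary cells shows the course of the same lineage without introduced genes. Zfp488 rose by 3.50 ± 0.04, from 15.8 ± 0.518 to 180 ± 2.73 CPM (n = 4 and 4, adjusted p = 1.90e-13), and Nkx2-2 fell by 1.82 ± 0.25, from 231 ± 7.78 to 65.7 ± 28.4 CPM (adjusted p = 3.56e-05). Myelin genes of the panel rose. Mbp (ENSRNOG00000016516) rose by 7.80 ± 0.08, from 232 ± 12.9 to 51538 ± 3929 CPM, Mog by 4.17 ± 0.08 and Myrf by 3.79 ± 0.06. Sox10 rose by 1.90 ± 0.06, Olig2 by 0.52 ± 0.05 and Olig1 by 0.41 ± 0.05, with 1 proliferating library apart from the others for Olig2. Mki67 fell by 1.96 ± 0.06 and Pdgfra, the PDGF receptor of progenitors, by 0.57 ± 0.04. Gfap, the astrocyte intermediate filament gene, rose by 7.97 ± 0.37, from 4.18 ± 0.238 to 1052 ± 467 CPM. Cspg4 differed by 0.16 ± 0.04 (adjusted p = 0.00428, but 0.338 with the CG4 libraries in the fit). Casr and Adgrg2, each with 4 counts in all over the proliferating libraries, went from 0.0308 ± 0.0266 to 124 ± 32.9 CPM and from 0.0313 ± 0.0223 to 15.3 ± 3.61 CPM. The largest rises also included the connexin gene Gjc3 (9.06 ± 0.12), the myelin gene Mobp (9.03 ± 0.12), Rpe65 (8.89 ± 0.19), Mylk (8.67 ± 0.11) and Nipal4 (8.01 ± 0.12). The largest falls were those of Cd93 (-8.94 ± 0.20), Vgf (-7.90 ± 0.16), Scg2 (-7.38 ± 0.08), Hmga2 (-7.09 ± 0.08), the monocyte receptor gene Cd14 (-7.06 ± 0.17), Aldh1a3 (-6.98 ± 0.19), Anxa3 (-6.86 ± 0.06) and Calca (-6.70 ± 0.10).

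In primary differentiation 28 of 29 myelin list genes rose and 1 fell (list adjusted p = 2.59e-35, and 0.00516 with an estimated correlation), Gpr37 by 7.27 ± 0.08. Of 14 committed or premyelinating genes 13 rose (1.02e-11, and 0.0101 estimated), with Tcf7l2 up 2.94 ± 0.04 and Tns3 up 2.49 ± 0.04. All 35 cell cycle genes fell (7.50e-19, and 0.00387 estimated), with Mcm5 at -2.30 ± 0.04 and Mcm7 at -2.12 ± 0.04. ERK feedback genes fell in 16 of 18 and rose in 2 (1.73e-10, and 0.0101 estimated), with the phosphatase genes Dusp6 at -3.39 ± 0.04 and Dusp4 at -4.85 ± 0.09. Thyroid hormone response genes rose in 6 of 9 and fell in 3 (0.000335, and 0.0352 estimated), with the receptor gene Thra up 2.80 ± 0.04 and Hr up 3.41 ± 0.05. All 22 cholesterol synthesis genes rose, with Hmgcs1 up 2.98 ± 0.10 and Mvk up 1.63 ± 0.07 (5.10e-05, but 0.593 estimated). Fatty acid and sphingolipid genes rose in 22 of 23, with Fa2h up 4.37 ± 0.06 and Ugt8 up 4.88 ± 0.10 (5.12e-08, but 0.251 estimated). Transcription factors of the lineage rose in 17 of 31 and fell in 8, with Sox11 at -3.46 ± 0.05 (0.00100, but 0.0683 estimated), and BMP pathway genes rose in 7 of 9, with Bmp4 up 3.78 ± 0.10 and Nog up 5.05 ± 0.17 (0.0420, but 0.250 estimated). For all of these lists the counts adjusted over the list alone were the same. In each bracket the first value is the list's adjusted p and the second the adjusted p with an estimated correlation.

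Markers of other cells moved with the medium in primary cultures. All 7 microglia and macrophage genes that had a name and were tested fell, 7 also adjusted over the list alone (list adjusted p = 9.42e-06, and 0.0126 with an estimated correlation). Csf1r, the receptor of colony-stimulating factor 1, went from 339.9 ± 5.84 to 14.1 ± 1.80 CPM and Laptm5 from 116 ± 4.43 to 17.5 ± 0.934 CPM. Interferon response genes fell in 16 of 22 and rose in 3 (list adjusted p = 0.0387, but 0.116 with an estimated correlation and 0.0598 with the replicate block), with Oasl at -5.43 ± 0.19 and Bst2 at -3.71 ± 0.13. Astrocyte genes rose in 12 of 15 and fell in 2 (list adjusted p = 2.35e-05, and 0.251 with an estimated correlation), with Fgfr3 up 3.67 ± 0.05 and the glutamine synthetase gene Glul up 2.83 ± 0.04. Neuron genes fell in 13 of 15 and rose in 2, with a median of -1.35 (list adjusted p = 0.318, and 0.611 with an estimated correlation), and fibroblast, pericyte and endothelial genes fell in 5 of 7 and rose in 2, with a median of -2.73 (0.406, and 0.762). Neither list passed against other genes. The counts of these lists adjusted over the list alone were the same. Of 12310 genes tested in primary cells 10439 passed, 5111 higher and 5328 lower, and 4736 of them differed by at least 1 on the log2 scale. The groups did not overlap for 81.4% of genes, against 2.86% by chance. The 4 differentiating libraries form 2 close pairs, 1 with 2 and 3 with 4 (Gfap at 1506 and 1433 against 657 and 636 CPM), so n = 4 may overstate how many independent cultures they stand for. With each pair summed 10435 genes passed.

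**Figure D4:**
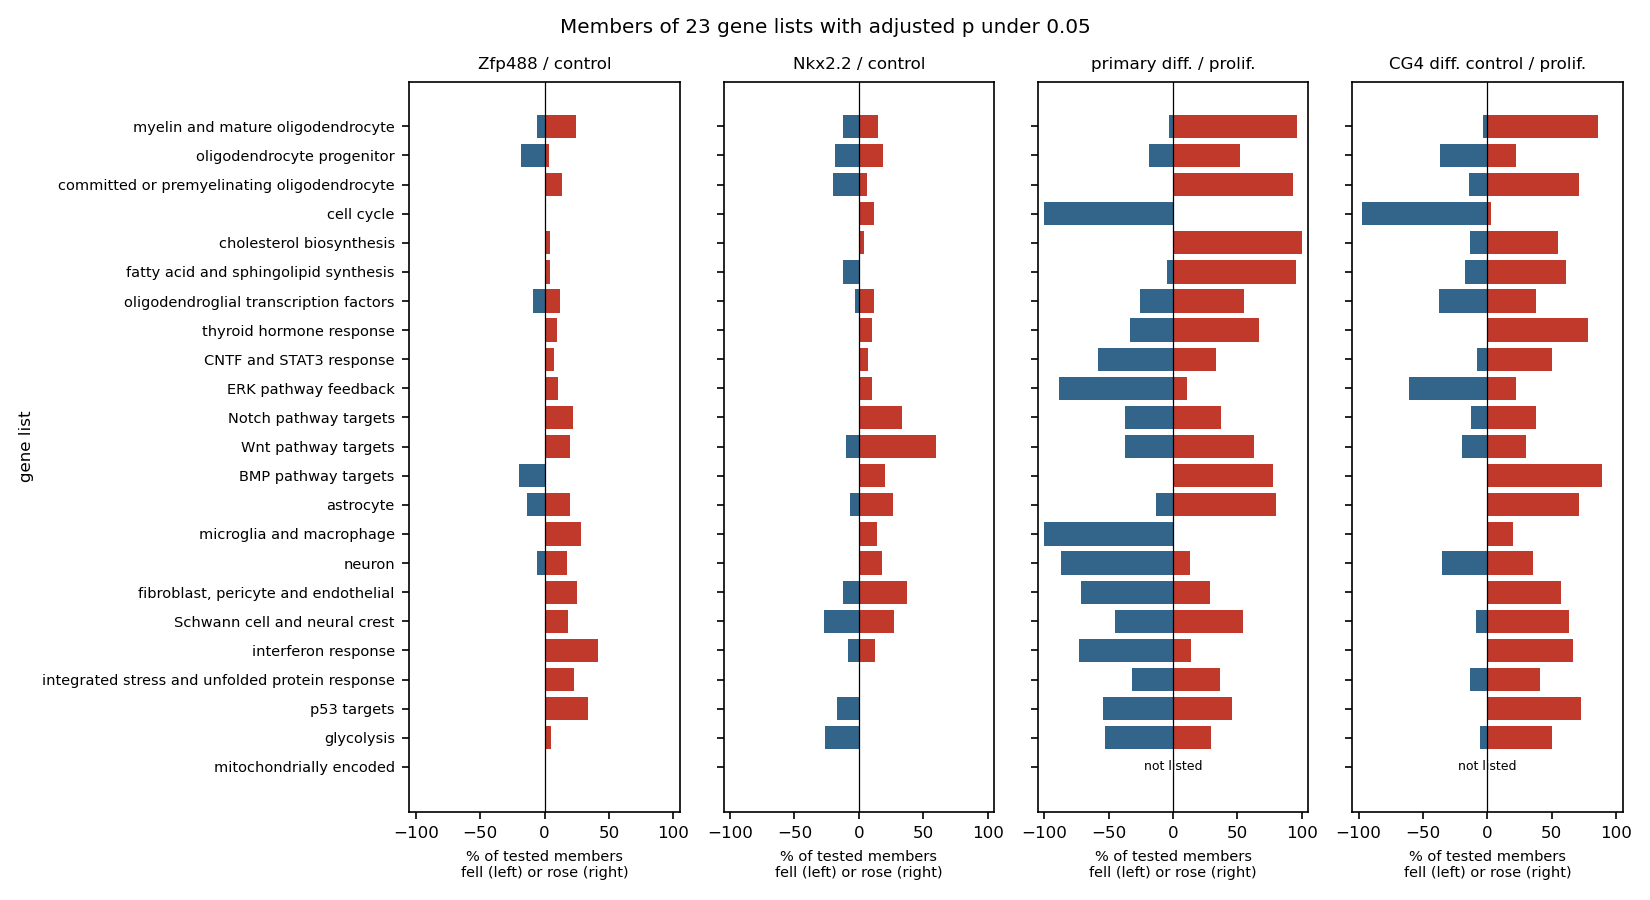
Share of each list's tested members that rose (right, red) or fell (left, blue) with an adjusted p under 0.05, for Zfp488 and Nkx2.2 against control, primary differentiation and CG4 differentiation of control cells. In primary cells 28 of 29 myelin genes rose and 35 of 35 cell cycle genes fell; with Zfp488 8 of 33 myelin genes rose.

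Differentiating control against proliferating CG4 cells asks how the line itself changes with the medium. The groups differ also in read length (150 against 100 bases) and in the GFP vector, which cannot be separated from the medium. Mog rose from 0.730 ± 0.566 (n = 3) to 40.1 ± 9.66 CPM (n = 4), a change of 5.75 ± 0.51 (adjusted p = 3.33e-05), Mbp by 3.93 ± 0.38, Myrf by 1.54 ± 0.31 and Sox10 by 1.01 ± 0.20. Gfap rose by 12.77 ± 1.28, from 0.176 ± 0.160 to 1330 ± 991 CPM. Nkx2-2 rose by 2.04 ± 0.36 and Zfp488 fell by 0.66 ± 0.22, from 68.0 ± 14 to 43.1 ± 11.4 CPM (adjusted p = 0.0274), a call that ended without control replicate 1, 2 or 4 or proliferating replicate 3 (up to 0.104). Mki67 fell by 3.09 ± 0.13, Pdgfra by 1.98 ± 0.26 and Olig1 by 1.48 ± 0.17. Olig2 (-0.40 ± 0.18, adjusted p = 0.0841) and Cspg4 (-0.71 ± 0.29, 0.0565) did not pass.

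Of the 8 largest rises 4 and of the 8 largest falls 7 were genes whose level in proliferating CG4 cells lay over 8-fold outside those of the other 3 groups without a factor. Another annotation or counting rule for the proliferating CG4 libraries may be the source. The folds of these genes may therefore not be changes in the cells. Best1 had 0 counts in the 3 proliferating CG4 libraries and stood at 160 ± 15.5 CPM in control, at least 1703-fold higher against a floor of 3 counts per library. Mcmdc2 likewise was at least 457-fold higher. Gapdh stood at 0.173 ± 0.0963 in proliferating CG4 cells against 2432 ± 215 CPM in control, and Eif4e2 at 0.0105 ± 0.0181 against 80.4 ± 7.93 CPM. Tpi1 (667 ± 379 against 0.900 ± 0.209 CPM), Gnas, Clip3, Abhd16b, Marf1, Rpl36a and Fam122b stood the other way, with log2 changes of -9.54 to -7.68. Group means under 1 CPM were set to 1 CPM for the 8-fold limit. The limit therefore does not clear genes at or near 0 of a counting difference. Among genes within that limit, Hhatl was at least 605-fold, Synpo at least 225-fold and Setdb2 at least 98.4-fold higher in control, against 0 counts. Myh6 (0.0184 ± 0.0164 to 154 ± 12.7 CPM) and Cyp2j10 (0.0160 ± 0.0139 to 42.3 ± 12.5 CPM) also rose from near 0, Entpd2 by 9.37 ± 0.67 and the growth factor gene Pdgfb by 9.09 ± 0.52. The falls included Nwd2 (-8.53 ± 0.57), Adam12 (-6.76 ± 0.38), Cfap52 (-6.53 ± 0.28), Dscam (-6.23 ± 0.95), Setbp1 (-5.24 ± 0.33), Zfp704 (-5.20 ± 0.27) and Dgkh (-4.98 ± 0.42).

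In CG4 differentiation cell cycle genes fell in 34 of 35 and rose in 1, with Kif11 at -3.33 ± 0.12 and Tyms at -4.94 ± 0.18 (list adjusted p = 3.20e-25, and 0.293 with an estimated correlation). Myelin genes rose in 25 of 29 and fell in 1, or 26 and 1 adjusted over the list alone, with Cldn11 up 6.96 ± 0.35 (7.76e-07, and 0.293). The cell cycle list holds E2f1, at 0.722 to 1.75 CPM in proliferating CG4 cells against 9.40 to 64.1 CPM in all others. The myelin list holds Tf, at 0.219 to 0.631 against 73.9 to 108 CPM. BMP pathway genes rose in 8 of 9, with Id1 up 3.81 ± 0.31 and Bambi up 2.10 ± 0.21 (0.00675, and 0.293). Astrocyte genes rose in 10 of 14, with Fgfr3 up 3.93 ± 0.31 (0.0163, and 0.293), and interferon genes in 14 of 21, with Irf9 up 2.03 ± 0.14 and Tap1 up 1.74 ± 0.18 (0.0174, and 0.639). Premyelinating genes rose in 10 of 14 and fell in 2, with Rras2 up 2.81 ± 0.13 and Lims2 up 5.32 ± 0.55 (0.0174, and 0.639), and thyroid hormone response genes in 7 of 9, with Bcl3 up 7.12 ± 0.78 and Dbp up 1.98 ± 0.25 (0.0409, and 0.433). Glycolysis genes rose in 9 of 18 and fell in 1 (0.0300, and 0.687), a list that holds Gapdh and Tpi1. Cholesterol synthesis genes rose in 12 of 22 and fell in 3, with Acat2 at -1.84 ± 0.11 (0.0467, and 0.687), a list that holds Fdps, at 15.8 to 25.2 CPM in proliferating CG4 cells against 390 to 1282 CPM in all other libraries. In each bracket the first value is the list's adjusted p and the second the adjusted p with an estimated correlation. For these lists, the myelin list apart, the counts adjusted over the list alone were the same. Fatty acid and sphingolipid genes passed only with the replicate block (adjusted p = 0.0707 without it and 0.0376 with it, but 0.687 with an estimated correlation and 0.653 with both), with 14 of 23 higher and 4 lower, or 13 and 3 with the block. So did CNTF and STAT3 response genes (0.176 and 0.0426, but 0.639 and 0.499), with 6 of 12 higher and 1 lower, or 4 and 1 with the block. The block fit of this comparison also left out control replicate 4, so its differences cannot be laid to the block alone. Of 12486 genes 8213 passed, 4064 higher and 4149 lower. The groups did not overlap for 67.2% of genes, against 5.71% by chance.

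The difference of the differentiation response between CG4 and primary cells was tested as an interaction, and it carries the read length and vector of the CG4 comparison. Zfp488 rose in primary cells and fell in CG4 cells, a difference of -4.12 ± 0.22 (adjusted p = 9.05e-10), and Nkx2-2 did the opposite, a difference of 3.90 ± 0.48 (adjusted p = 4.34e-06). The CG4 response was lower for Mbp (-3.82 ± 0.34), Myrf (-2.2 ± 0.30), Olig1 (-1.84 ± 0.17), Pdgfra (-1.36 ± 0.25), Mki67 (-1.09 ± 0.12), Olig2 (-0.87 ± 0.18), Sox10 (-0.84 ± 0.19) and Cspg4 (-0.82 ± 0.18), and higher for Gfap (4.82 ± 1.11) and Mog (1.61 ± 0.39). The response of all 7 microglia genes was less negative or more positive in CG4 cells. Csf1r and Lyz2 fell in primary cultures, while in CG4 cells they stood at 0.0634 and 0.178 CPM in proliferating and 0.249 and 1.63 CPM in control libraries, far under their primary levels (list adjusted p = 0.000983, and 0.0943 with an estimated correlation). The response was also higher in CG4 cells for 18 of 22 interferon genes and lower for 1, with Irf9 at 2.26 ± 0.14 and Tap1 at 3.37 ± 0.22 (0.000232, and 0.256). In CG4 cells the response was lower for 17 of 22 cholesterol genes and higher for 3, with Acat2 at -2.91 ± 0.17 (0.0107, and 0.654), lower for 14 of 23 fatty acid and sphingolipid genes and higher for 3, with Sptlc2 at -2.63 ± 0.12 and Ugt8 at -3.29 ± 0.21 (0.0107, and 0.621), and lower for 11 of 14 premyelinating genes and higher for 1, with Itpr2 at -4.28 ± 0.24 and Rras2 at -3.03 ± 0.24 (0.0271, and 0.621). Transcription factors of the lineage were lower in 18 of 32 and higher in 5, with Tcf12 at -2.12 ± 0.14 (0.0454, and 0.621). Of 11 p53 targets 7 were higher, with Plk2 at 4.61 ± 0.25 and Aen at 2.36 ± 0.13 (0.0211, and 0.621), and of 18 glycolysis genes 10 were higher and 4 lower, with Pkm at 2.32 ± 0.26 (0.0478, and 0.654, but 0.0648 with the replicate block). The counts of these lists adjusted over the list alone were the same, and the second value in each bracket is the adjusted p with an estimated correlation. Further lists passed only with the replicate block: myelin, with 19 of 29 genes lower and 3 higher, or 18 and 3 with the block (adjusted p = 0.0536 without and 0.00752 with the block), cell cycle, with 22 of 35 lower and 4 higher, or 24 and 4 (0.0533 and 0.00752), CNTF and STAT3 response, with 9 of 12 higher and 2 lower in both fits (0.156 and 0.0391), ERK feedback, with 10 of 18 higher and 4 lower, or 11 and 3 (0.103 and 0.0371), and fibroblast, pericyte and endothelial, with 4 of 8 higher, or 5 (0.103 and 0.0391). With an estimated correlation they had adjusted p of 0.621 to 0.697, and with both 0.421 to 0.512. The glycolysis, cholesterol, myelin and cell cycle lists hold Gapdh, Tpi1, Fdps, Tf and E2f1, whose levels in proliferating CG4 cells enter here too. Of 13207 genes 9146 passed, 4467 higher in CG4 cells and 4679 lower. Of the 8 largest differences 5 upward and 6 downward were genes that lay over 8-fold outside those groups in proliferating CG4 cells, and no fold is given for them.

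The response to each factor was then set beside primary differentiation, with which it shares no library. Across 11722 genes, which are not independent, the Zfp488 response correlated with primary differentiation at r = 0.163 (rho = 0.192), with a two-sided exact permutation p = 0.371 over the 70 assignments of the 8 CG4 libraries. The Nkx2.2 response correlated at r = -0.0533 (rho = -0.0961, exact permutation p = 0.771). The smallest p this permutation allows is 0.0286, and neither correlation passed. This permutation also mixes the shared deviations of same-numbered libraries into its chance values, which the real comparison balances. Exchanging labels only within the 4 pairs gave an exact permutation p = 0.25 for Zfp488 and 0.625 for Nkx2.2 over 16 assignments, where the smallest possible p is 0.125, so this version, added after the result was seen, could not pass. By pair, r was 0.114 to 0.152 for Zfp488, above 0 in 4 of 4 pairs, and -0.0974 to 0.0281 for Nkx2.2, above 0 in 1 of 4.

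The deposited tables of the authors hold their own tests of each factor against control. For Zfp488 the authors' table lists 14441 genes, of which 2023 have an adjusted p under 0.05, 1307 higher and 716 lower. Of the 1339 genes called here 1313 are among these, all in the same direction, and the log2 changes correlate at r = 0.99996 across 14429 genes. For Nkx2.2 it lists 14581 genes with 2098 under 0.05, 1169 higher and 929 lower, and 1517 of the 1567 genes called here are among these, all in the same direction (r = 0.999905 across 14553 genes).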

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

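The tests of a shared batch, of a counting rule, of microglial RNA and of a lower share of oligodendroglia were chosen after the result was seen, and those of depth, progress of differentiation and proliferation before.

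Of 70 groups of values tested (library totals and panel genes in CPM, in groups of 4), 3 held a library whose gap to its nearest neighbour exceeded Dixon's 95% critical value as a share of the range, and chance gives about 1 in 20. They are Sox10 in control replicate 1 (1507 CPM, the others 1621 to 1641), Olig1 in Nkx2.2 replicate 3 (513 CPM, the others 316 to 345) and Olig2 in proliferating primary replicate 2 (727 CPM, the others 767 to 775). The scale of this test was not fixed before the data were examined. The differentiation response differed between CG4 and primary cells for 9146 genes by the interaction term.

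Libraries with the same number deviated together in differentiating CG4 cells. A difference of depth is argued against, since the median correlation of same-numbered libraries was 0.418 after thinning to equal totals. A shared culture or library batch stays open. The median correlation of 0.443, against -0.0990 for differently numbered libraries, is the pattern itself and so lends it no support over another shared source, and the labels name no batch. The first component of the deviations, 70.5% of their variance, correlated across 11722 genes with primary differentiation at 0.226, between the bounds set for progress of differentiation, so this explanation stays open. A batch and a different pace of differentiation in each culture could also act together.

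In proliferating CG4 cells 286 of the shared genes lay over 8-fold outside the primary groups and control, 187 above and 99 below, with group means under 1 CPM set to 1 CPM. These genes enter the difference between CG4 and primary cells. Proliferation as a state shared with primary cells was weighed as the source. Of the 190 tested ones 16.3% (95% confidence interval 11.4% to 22.4%) moved the same way in primary cells, under the bound set before. The interval treats genes as independent. Of other genes 20.4% fell by at least 1 on the log2 scale in primary differentiation, also under that bound. The genes were chosen to lie outside proliferating primary cells too, which lowers their share, so this test cannot decide on proliferation. By that choice the levels differ as well: proliferating primary libraries stood at 1218 to 1380 CPM of Gapdh and 165 to 200 CPM of Best1, which had 0 counts in proliferating CG4 libraries. An effect of proliferation in CG4 cells alone cannot be separated from the medium and stays open. Another annotation or counting rule for these libraries may be the source: 6 genes were at 0 in every one of them and at 5 CPM or more in each of the other 20 libraries, and 16 the other way round. Gapdh stood at 0.0626 to 0.243 CPM there and at 984 to 3004 CPM elsewhere. The read length, the vector and the medium cannot be separated for the remaining genes of this comparison.

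Of 20 microglia and macrophage genes, the 7 that had a name and were tested all fell in primary differentiation. The others may have been counted without a name. A lower share of oligodendroglia that raises every other cell type alike in proliferating cultures is argued against as the only change, since the astrocyte list's median rose by 3.02, with 12 of 15 members rising. A change in the astrocyte genes themselves stays open, and 10 of 14 also rose in differentiating CG4 cells. Neuron genes (13 of 15, median -1.35) and fibroblast, pericyte and endothelial genes (5 of 7, median -2.73) fell with the microglia genes, so a lower share that raised these types and not astrocytes stays open as well. RNA of microglia in the proliferating cultures may be the source, since the median marker stood at 94.5 CPM there and 0.178 CPM in the proliferating cell line, a ratio of 530. The most abundant, in CPM scaled over all libraries, were Lyz2 (755, and 14.3 in differentiating cells), Csf1r (356 and 14.3) and Laptm5 (122 and 17.8). Cd68 stood at 94.5 and 6.53, and at 4.10 in the cell line, which also expresses some of these genes. A change of these genes in the same microglia was not tested.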

How the results depend on the processing

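The fits without libraries numbered 3, with close replicates summed, with comparable genes only and with the replicate block together with an estimated correlation were chosen after the result was seen.

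With the replicate block 3576 genes passed for Zfp488, 3876 for Nkx2.2 and 6276 between the factors, where the numbers pair the libraries and the block takes up their shared deviation. DESeq2 gave 2116 genes for Zfp488, and the cause was not tested. RLE size factors, no filter, thinning, only the compared libraries and leaving out the libraries numbered 3 gave 1045 to 1363 genes for Zfp488, 1297 to 2158 for Nkx2.2 and 3294 to 4130 between the factors. DESeq2 gave 2317 and 4466 for the last comparisons. Without 1 library in turn the counts were 458 (without Zfp488 replicate 4) to 1604 (without Nkx2.2 replicate 3), 924 (without Nkx2.2 replicate 4) to 2302 (without Nkx2.2 replicate 3) and 2585 to 4636.

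In primary cells all settings, the replicate block included, gave 9402 to 11057 genes, in CG4 differentiation 6556 to 9816 and for the interaction 8527 to 9467. Without 1 library in turn these were 10186 to 10448, 7360 to 8424 and 8789 to 9545. The numbers do not pair these libraries (correlations of -0.0443 to 0.103 in primary and -0.130 to 0.0449 in CG4 cells), and not every library correlated best with its own number. The block took the counts to 10413, 6556 and 8527. In CG4 differentiation the block fit also left out control replicate 4, which has no proliferating library of its number. Leaving out that library alone gave 7360.

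The correlation with primary differentiation was 0.0989 to 0.221 for Zfp488 and -0.0841 to -0.00736 for Nkx2.2 without 1 library in turn, and passed in no setting. The correlation of both responses was 0.0514 with the controls split, which removes the shared controls, and 0.124 to 0.223 without 1 library in turn. Of the gene list tests 58 passed, 7 with an estimated correlation, 1 with the replicate block and estimated correlation, 66 with the replicate block alone, 85 with fry for 1 direction and 126 with fry for either direction. The cause of the difference between these counts was not tested.

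Over 290 pairs of a named gene and a comparison, 5010 values kept direction and side of the threshold, 79 no longer passed, 36 newly passed and 15 changed sign, each uncalled in both. In the Zfp488 comparison Gfap went to 0.07 and 0.0905 without control replicate 1 and 2, 0.03 without Zfp488 replicate 3 and 0.0198 with the replicate block (from -0.61 over the libraries left out). Pdgfra in Zfp488 against control in differentiating CG4 cells went to -0.00746 without control replicate 3 and -0.00249 without Zfp488 replicate 2 (up to 0.22), and Cspg4 to -0.0241 without Zfp488 replicate 1 (up to 0.47). In the Nkx2.2 comparison Gfap went to 0.30, 0.32 and 0.33 without control replicate 1, control replicate 2 and Nkx2.2 replicate 3 and to 0.00314 with the replicate block (down to -0.47). Myrf went to 0.0932 without Nkx2.2 replicate 1 (down to -0.24). Between the factors Gfap went to 0.05 without Zfp488 replicate 3, 0.20 without Nkx2.2 replicate 2 and 0.0166 with the replicate block (down to -0.59). The cause of these changes was not tested. Except for the lists named in the results, the block changed no call of these genes or lists from passing to not passing. Depth limits genes near 0 counts. Only a lower bound of the fold is given for the named genes at 0 in every library of a group, and folds from a few counts, as of Gfap in CG4 differentiation, are given with their SE.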

Other observations

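All tests here were chosen after the result was seen.

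The 2144 genes that rose in primary differentiation were higher with Zfp488 by a mean log2 change of 0.236, in 4 of 4 pairs of same-numbered libraries (two-sided exact permutation p = 0.0286, the smallest this permutation allows, adjusted 0.0571 over the 6 tests). Of them 347 rose and 68 fell, 16.2% rising against 3.68% of other genes. Other genes here are all those tested in CG4 cells outside the rising and falling sets. Of the 14811 genes tested in CG4 cells only 11722 were tested in primary cells too, so the other genes are not a matched background. With Nkx2.2 their mean change was 0.0126, above 0 in 2 of 4 pairs (exact permutation p = 0.8), with 166 rising and 195 falling. Between the factors they were higher with Zfp488 by 0.223, in 4 of 4 pairs (exact permutation p = 0.0286, adjusted 0.0571), with 28.0% higher against 10.5% of other genes and 9.05% lower against 10.9%. The 2136 genes that fell in primary differentiation changed by a mean of 0.0682 with Zfp488, also above 0 in 4 of 4 pairs (exact permutation p = 0.257), with 138 rising and 94 falling (6.46% rising against 3.68% of other genes, and 4.40% falling against 2.89%). With Nkx2.2 they changed by 0.142, above 0 in 4 of 4 pairs (exact permutation p = 0.0286, adjusted 0.0571), with 236 rising and 91 falling. Between the factors they differed by -0.0738, above 0 in 1 of 4 pairs (exact permutation p = 0.229), with 20.2% lower with Zfp488 against 10.9% of other genes and 12% higher against 10.5%. Zfp488 may raise part of the genes that rise in primary differentiation, with the mean of 0.236 above. Against control the genes that fall there did not fall with it on average. The adjusted values decide nothing, since 3 of the 6 tests stand at the smallest p the permutation allows and adjustment takes that to 0.0571. A move toward the profile of differentiated primary cells therefore stays an open hypothesis.

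The counts of genes were compared with other splits of the same libraries. In each comparison 1 split, the real one, gave as many genes, of 35 splits (100 drawn for the interaction). For CG4 differentiation, where the numbers do not pair the libraries, chance assignment can be excluded at a share under 0.05. The real count was 8213 and the highest of the other splits 0. For the interaction they were 9146 and 6002, the latter in a split that kept the CG4 groups and exchanged primary libraries. The interaction splits exchange libraries between media within each cell source, which breaks the responses themselves. They cannot tell what equal responses would give, so nothing is concluded from them. With each close pair of differentiating primary libraries summed, the interaction gave 8606 against a highest other of 3777 over 40 splits, 1 of them as large. For primary cells the real count and the highest other were 10439 and 0. With the close pairs summed they were 10435 and 0 over 15 splits, too few for a share under 0.05. In differentiating CG4 cells the numbers pair the libraries, and only 8 splits part all 4 pairs, too few for a share under 0.05. Among these the real counts and the highest other were 1339 and 0 for Zfp488, 1567 and 0 for Nkx2.2 and 3741 and 0 between the factors. The other splits keep some libraries of 1 number on the same side. Among all 35 the highest others were 1 for each factor against control and 2171 between the factors, the latter in a split that exchanged Zfp488 replicate 1 and Nkx2.2 replicate 3, the lowest and highest libraries of those groups on the component that separates the numbers. They are also the libraries of their groups nearest to 0 on component 1, which separates the factors (-15.3 and 19.1), so this exchange leaves the more extreme libraries of each factor on their own side. The replicate block gave 6276 there.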
